A study of Danio rerio with 25 samples.

How the data were processed

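Small RNA was sequenced from brain samples of male zebrafish (Danio rerio, strain AB JxTü) at 6, 12, 24, 36 and 42 months of age, with 5 libraries per age and 25 in all. Tissue, sex and age are given per the labels, and the labels state no dissection details. Per the submitters' protocol notes, total RNA was converted to libraries with the Illumina TruSeq small RNA kit. The submitters' processing notes name CASAVA 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9. The genome build, the miRNA annotation, the counting program and the handling of reads that match several places are not given in the sources used here. The deposited table holds 1 raw count per hairpin and library, and the values were checked to be whole numbers without scaling by the authors. All 25 count columns were used, so that columns not used numbered 0.

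The deposited table lists 346 hairpin entries, of which 17 have a total of 0. Hairpins that are numbered copies of the same miRNA were summed by name to 217 miRNAs. Of these, 51 names have several copies, and in 34 of them the copies hold counts within 10% of equal, as when reads matching several copies are shared out. Reads from both arms of a hairpin are in 1 count, so that no arm is named. Members with nearly identical mature sequences, such as those of let-7, miR-10, miR-29, miR-101, miR-203 and miR-200/429, can share reads, and how far they do is not known here. miRNAs were kept for testing with filterByExpr (count minimum 10, total minimum 15, age as the group), which kept 197 and left out 20. The tested miRNAs hold nearly all counts in every library.

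Libraries were grouped by age alone. The line follows age: no transgene is named at 6 and 24 months, Tg(flk:mCherry) is named at 12 months, Tg(pu.1:GFP) at 36 months and Tg(wt1a:GFP) at 42 months. Line and age therefore could not be separated except in 24 against 6 months. The titles of the 6-month libraries hold 2 animal numbers each and the others 1, and what this means is not stated. Replicates are numbered in order of deposit within an age and carry no pairing across ages. Nothing beyond the labels says that replicates are independent animals, so that p-values measure the spread between these samples. No batch or date is given in the labels. The animal numbers in the titles run in separate blocks by age. Any order of handling that they reflect therefore cannot be separated from age, also in 24 against 6 months.

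Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, a quasi-likelihood fit with robust dispersion on all 25 libraries and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over the 197 miRNAs within a comparison, and a miRNA was called at an adjusted p under 0.05. The comparisons were any difference between the 5 ages, a linear trend on age (log2 units per year), departure from that line, 42, 36, 24 and 12 against 6 months, and the successive steps 24 against 12, 36 against 24 and 42 against 36 months. The standard error of a log2 change is approximated from the F statistic. Levels are CPM, counts scaled by TMM-adjusted library size, given as mean ± SD over 5 libraries. Summed CPM of a list and the choice of libraries with high epithelial miRNA content use library totals. A prior count of 2 was used on the log2 CPM scale. Summaries of total count and composition were compared by two-sided exact permutation tests over all 252 splits of 5 against 5 libraries, whose smallest p is 0.00794, and by 100000 permutations for correlations with age. Agreement between 24 against 6 months and 42 against 12 months, which share no library, was tested by 10000 shuffles of age within each pair. Ranges given for counts of 0 allow up to 3 counts, and such limits cover counting error only.

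26 lists of miRNAs (families, clusters, cell types and tissues) were drawn up from general knowledge before the data were examined, and 25 of them have at least 2 tested members. They cover the let-7, miR-17-92, miR-29, miR-15/16, miR-23/24/27, miR-26/101, miR-30, miR-181, miR-34, miR-130 with miR-301 and miR-454, miR-200 and miR-182 with miR-183 and miR-96 groups, miRNAs of neurons, neuronal activity, oligodendrocytes, endothelium, red blood cells, immune cells, muscle, epidermis, gut with liver and pancreas, pituitary and endocrine cells, eye with choroid plexus and pigment, vascular smooth muscle and the Hox clusters, and miR-430. Besides miR-10 and miR-196, the Hox cluster list holds miR-99, miR-100 and miR-125, which are not Hox cluster miRNAs. The list of miR-130, miR-301 and miR-454 also holds miR-455. Lists were tested for the trend, 42 against 6 and 24 against 6 months with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, in limma 3.58.1, with adjustment over the 25 lists. The p-value of fry tests whether the members of a list move, on balance, in 1 direction. The grouping, tests, lists and most other settings were fixed before the data were examined, and so was the rule for naming miRNAs. That rule takes the 5 most abundant miRNAs, the largest changes in each direction among calls with a mean of at least 10 CPM (12 each way for the trend and 42 against 6 months, 8 for 24 against 6, 4 for 12 and 36 against 6, 3 for each successive step), the 5 smallest p-values for departure from the line, and up to 4 members per list with the smallest trend p. A miRNA named outside it is said to be chosen after its values were seen.

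The other settings fixed beforehand were DESeq2 size factors, library totals without TMM, no count filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, leaving out the 5 most abundant miRNAs, each library in turn, or (for the trend) each age in turn, a contrast of group means, log2 of age, and a Spearman permutation test. For pairs of ages a fit of the 10 libraries concerned was added. After the data were seen, 3 more settings were added for every comparison: hairpin entries without summing copies, the data without 7 libraries rich in epithelial miRNAs (miR-200 list or epidermis list above 2000 CPM, a limit set from the data), and the log2 summed CPM of these 2 lists as covariates. A reference gene table (GRCz12tu) was used for the names and neighbours of miRNAs only; it gave a position for 195 of the 197 names. Calls were tested on simulated data: with 20 miRNAs changed 2-fold and 20 others changed 1.5-fold among 197, the comparisons recovered between 70% and 85% of the former, with 0 to 2 false calls among 157 unchanged miRNAs. Simulated counts were drawn independently for each miRNA, whereas miRNAs vary together in the real libraries. The number of false calls therefore does not carry over to them. Random splits of the real libraries gave up to 30 calls, for departure from the line. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Replicate libraries were checked for duplicated data by the smallest chi-square per degree of freedom between pairs, 113, which excludes copies of a library.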

Results

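Small RNA was sequenced from the brains of male zebrafish at 6, 12, 24, 36 and 42 months of age, with 5 libraries per age. Total miRNA counts averaged 5781400 ± 1791300 (SD, n = 5, range 3983783 to 8072968) at 6 months, 9466100 ± 4419500 (5993186 to 16993499) at 12 months and 7577900 ± 2264700 (5632881 to 10196781) at 24 months. They averaged 9872500 ± 6328400 (5237318 to 20924118) at 36 months and 9411400 ± 2745400 (7141523 to 14020920) at 42 months. Between 200 and 206 miRNAs were detected per library. The median correlation of log2 levels between libraries of an age was 0.972, 0.978, 0.984, 0.979 and 0.975 from the youngest to the oldest.

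miR-181a was the most abundant miRNA, at 266100 ± 21460 CPM at 6 months and 239100 ± 12950 CPM at 42 months. It was followed by miR-128 (64800 CPM at 6 and 82410 at 42 months), let-7a (51560 and 62140), miR-9 and miR-21 (31030 and 34230). miR-181a took 28.05% ± 1.23 of counts at 6 months and 23.9% ± 1.93 at 42 months, a difference of -4.19 percentage points that was the smallest p the 252 exact splits can give (exact permutation p 0.00794, adjusted over 8 comparisons 0.0635). Without 24-month replicate 2 the adjusted p was 0.0317 for this and for 24 against 6 months, where the difference was then -2.69 in place of -1.61 points. Its share decreased with age across the 25 libraries by rank (Spearman -0.561, permutation p 0.00439, adjusted over 4 relations 0.0176). Pearson's r was -0.459 (permutation p 0.0214, adjusted 0.0854), and -0.463 (p 0.0277) without the 2 libraries farthest from the median. Total counts of 42- and 6-month libraries did not differ beyond the spread of libraries (exact permutation p 0.0556, adjusted 0.148). On TMM-scaled levels, neither miR-181a nor miR-9 had a trend with age, and the slope of miR-128 was 0.10 per year (SE 0.04, adjusted p 0.0544).

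The question put to the 5 ages was which brain miRNAs change as the fish grow old. miR-29b, a family member known for repressing collagens and other matrix genes, rose from 187 ± 23.2 CPM at 6 months to 488 ± 171 at 36 and 389 ± 76.7 at 42 months, a slope of 0.45 log2 units per year (SE 0.07, adjusted p 1.83e-05, n = 25). miR-29a rose from 935 ± 62.2 to 1569 ± 176 CPM (0.22 per year, adjusted p 8.51e-05). miR-101a rose from 6236 ± 943 to 10680 ± 1765 CPM (0.24 per year, adjusted p 1.43e-04) and miR-101b from 221 ± 29.8 to 408 ± 49.5 CPM (0.26 per year, adjusted p 1.83e-05). miR-146b, which damps innate immune signalling, rose from 139 ± 34.7 to 280 ± 27.7 CPM (0.26 per year, SE 0.05, adjusted p 4.45e-04), and miR-26b from 27570 to 33600 CPM (0.12 per year, adjusted p 6.50e-04).

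In the same trend test 3 members of the miR-15/16 group, which represses cell-cycle genes, fell together. miR-15b went from 812 ± 94.1 CPM at 6 months to 373 ± 31.6 at 24 and 345 ± 71.8 at 42 months (-0.42 per year, SE 0.05, adjusted p 1.81e-06). miR-15c went from 66.1 ± 5.63 to 19.8 ± 3.43 CPM (-0.57 per year, adjusted p 3.44e-06) and miR-457a from 183.3 ± 7.08 to 69.5 ± 14.3 CPM (-0.47 per year, adjusted p 1.81e-06). miR-30c fell from 2366 ± 156 to 1876 ± 128 CPM (-0.13 per year, adjusted p 7.16e-04). Among miRNAs with a mean of at least 10 CPM, the largest falls in slope were those of miR-375, known from endocrine cells, at -0.99 per year (SE 0.33, adjusted p 0.0329), miR-725 at -0.95 and the skin miRNAs miR-205, miR-203b and miR-203a at -0.90, -0.81 and -0.78. The mesenchymal miR-199 (-0.53) and miR-214 (-0.51), the red blood cell miR-144 (-0.37) and miR-34c (-0.37) fell as well. Further rises were miR-15a (0.21), miR-1388 (0.20), miR-125c (0.12), the oligodendrocyte miR-338 (0.12), let-7a (0.12) and miR-22a (0.10 per year).

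**Figure D1:**
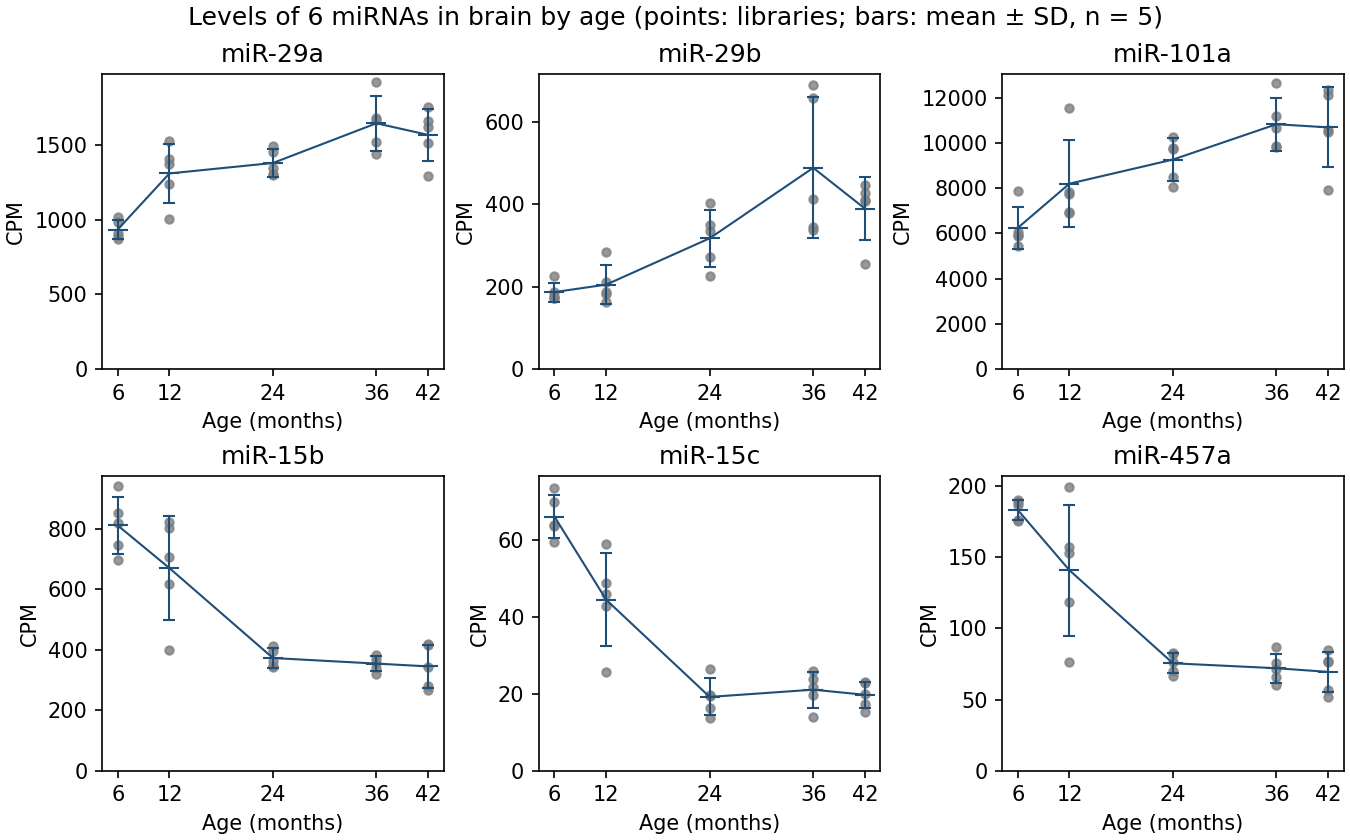
Levels (CPM, linear axis from 0) of miR-29a, miR-29b, miR-101a, miR-15b, miR-15c and miR-457a against age in months; points are libraries and bars the mean ± SD of 5. miR-29b averaged 187 CPM at 6 and 389 at 42 months, and miR-15b 812 and 345.

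Of 197 miRNAs, 42 had a linear trend with age, 15 up and 27 down, and 74 had an unadjusted p under 0.05. The calls rested on the ends of the age range, since 15 miRNAs were called without the 6-month group and 11 without the 42-month group. miR-29b, miR-101a, miR-101b, miR-26b, miR-15b, miR-15c, miR-457a and miR-30c kept the call in every setting fixed beforehand and without any single library. miR-375 was not called with limma-voom (-0.72 per year, adjusted p 0.0677) or log2 of age (0.0506), and miR-338 (0.0832), let-7a (0.0630) and miR-22a (0.0817) were not with library totals only. Without the 6-month group the slopes of miR-338 (0.03, adjusted p 0.783), miR-1388 (0.07, 0.554), miR-125c (0.08, 0.276), miR-144 (-0.20, 0.296) and miR-34c (-0.16, 0.496) shrank and were not called, and those of miR-15a (0.18, 0.276), let-7a (0.13, 0.121), miR-22a (0.13), miR-375 (-0.95, 0.226), miR-203a (-0.84, 0.0631), miR-199 (-0.45, 0.0919) and miR-214 (-0.39, 0.102) were not called either. miR-29a and miR-146b missed it without the 6-month group (adjusted p 0.0504 for each), as miR-146b did without the 42-month group (0.0621). Without the 42-month group miR-725 (-0.86, 0.0657), miR-205 (-0.80, 0.107), miR-203b (-0.76, 0.0891), miR-203a (-0.62, 0.174), miR-375 (-0.69, 0.325), miR-125c (0.08, 0.204) and miR-22a (0.06, 0.445) were not called. Neither were miR-15a, miR-1388, miR-338, let-7a, miR-199, miR-214, miR-144 and miR-34c (adjusted p 0.0597 for miR-214 to 0.0944 for miR-34c). Leaving out 1 library ended the call of miR-375 (adjusted p 0.155 without 6-month replicate 2 and 0.0724 without 6-month replicate 5, and between 0.0502 and 0.0590 without 36-month replicate 5 or 42-month replicate 1, 3, 4 or 5), miR-15a (0.0601 without 6-month replicate 2, 0.0559 without 42-month replicate 5) and miR-34c (0.0587 without 6-month replicate 1). It also ended that of miR-338 (0.0529 to 0.0696 without 6-month replicate 1, 2, 3 or 5), let-7a (0.0502 to 0.0641 without 6-month replicate 2 or 3 or 42-month replicate 5) and miR-22a (0.0528 to 0.0783 without 6-month replicate 2 or 5, 12-month replicate 1, 3 or 5, 36-month replicate 5 or 42-month replicate 1, 2 or 5).

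Part of the variation between libraries lay in miRNAs known from epithelia. Summed CPM of the miR-200 family, a group typical of epithelial cells, averaged 3956 ± 4235 at 6 months, 841 ± 1167 at 12, 207 ± 111 at 24, 1779 ± 3547 at 36 and 190 ± 158 at 42 months. The skin miRNAs miR-203a, miR-203b and miR-205 together averaged 1523 ± 1372, 2067 ± 1979, 281 ± 214, 574 ± 322 and 247 ± 168 CPM. In 7 libraries the sum of either list was above 2000 CPM, a limit chosen after seeing the data: 6-month replicates 1, 2 and 5, 12-month replicates 3, 4 and 5 and 36-month replicate 1. Without these libraries, which left 2 at 6 and 2 at 12 months, 9 miRNAs kept a linear trend, and all 9 were among the 42: miR-29a, miR-29b, miR-101a, miR-101b, miR-146b, miR-26b, miR-15b, miR-15c and miR-457a. miR-30c was not called then, at a slope of -0.11 (SE 0.04, adjusted p 0.0895) in place of -0.13 (SE 0.03), with -0.16 (SE 0.03) with the covariates described next. Neither were miR-375 (-0.57, SE 0.62, in place of -0.99, SE 0.33, and -0.41 with the covariates), miR-725 (-0.39, SE 0.24, in place of -0.95, SE 0.23, and -0.22), miR-199 (-0.22 in place of -0.53), miR-214 (-0.23 in place of -0.51), miR-144 (-0.28, SE 0.12, in place of -0.37, SE 0.09) or the skin miRNAs miR-203a, miR-203b and miR-205 (-0.14, -0.20 and -0.14, in place of -0.78, -0.81 and -0.90). With both list sums as covariates 19 miRNAs were called, which included those 9 and miR-30c. Not all of the 19 were among the 42. Of the 39 trend calls that the naming rule takes in, 12 stayed called. Others, such as let-7d, miR-181b and miR-92b, were called with the covariates but not in the main trend. For the miR-200 family, miR-203 and miR-205 themselves these settings remove what is measured and decide nothing.

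**Figure D2:**
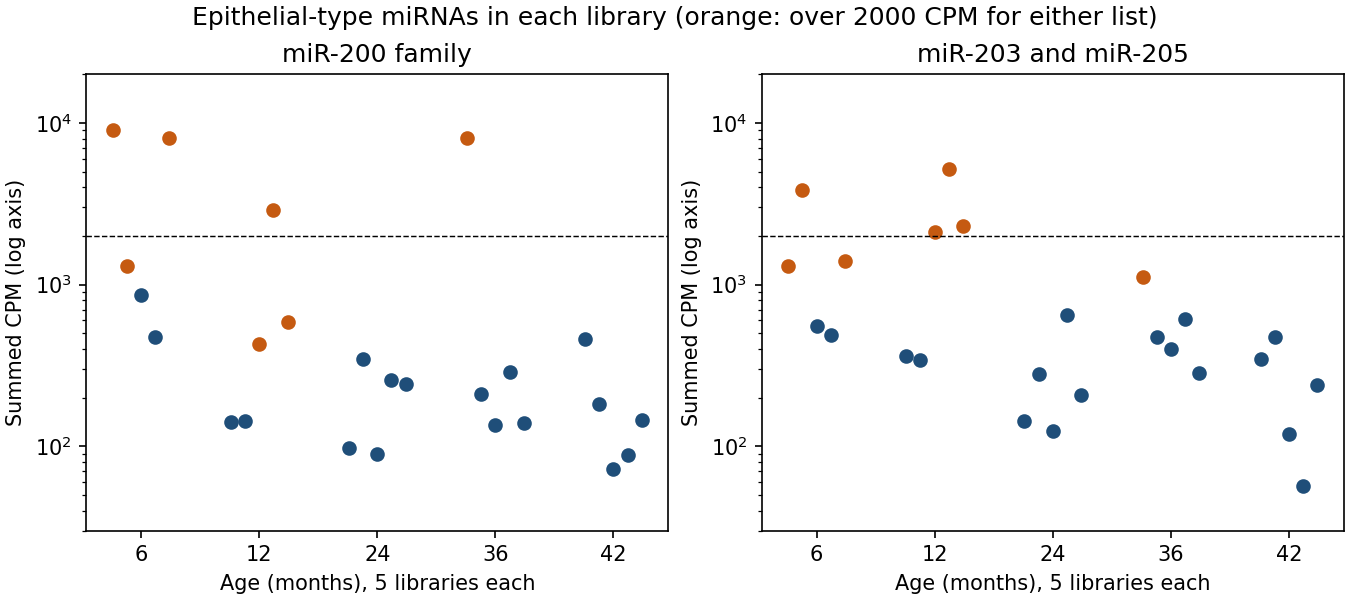
Summed CPM (log axis) of the miR-200 family and of miR-203 with miR-205 in each of the 25 libraries by age in months; orange points are the 7 libraries above 2000 CPM (dashed line) for either list. Every 24- and 42-month library lies below the line in both panels.

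Age was compared in fish with no transgene named in either group at 24 and 6 months, the only such pair. miR-29a (log2 change 0.56, SE 0.10, adjusted p 5.42e-04), miR-29b (0.76, SE 0.21, adjusted p 0.0153), miR-101a (0.57, SE 0.14, adjusted p 0.00727), miR-146b (0.71, SE 0.16, adjusted p 0.00573) and miR-1388 (0.73, adjusted p 0.00757) were higher at 24 months. miR-15c (-1.78, SE 0.21, adjusted p 4.15e-06), miR-457a (-1.28, SE 0.18, adjusted p 3.83e-05) and miR-15b (-1.12, SE 0.16, adjusted p 3.83e-05) were lower. miR-10b (1.23, adjusted p 0.0412), miR-10d (1.15, adjusted p 0.0494), both from Hox clusters, and miR-221 (0.66, adjusted p 0.0381) were higher near the threshold. The largest falls were those of the miR-200 family, from -3.78 for miR-141 to -5.96 for miR-429b (SE 1.86, adjusted p 0.0231), with miR-205 at -2.53 (adjusted p 0.0231) and miR-203a at -2.12.

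In 24 against 6 months 63 of 197 miRNAs were called, 27 higher and 36 lower, and 85 had an unadjusted p under 0.05. For 35 of the 197 all 5 libraries of an age lay above all 5 of the other, which chance gives for 0.794% of miRNAs, and 33 of these were called. Scaling moved the balance: with library totals only, 8 were higher and 54 lower, and the median log2 change of all miRNAs was -0.14 in place of 0.04. The count fell to 39, 36 and 27 without 6-month replicate 1, 2 or 5 and to 31, 24 and 31 without 24-month replicate 1, 3 or 5. miR-10d was not called in 7 settings fixed beforehand (adjusted p from 0.0513 with DESeq2 size factors to 0.0951 with library totals only), miR-10b in 3 (library totals only, 0.0769; a minimum of 10 CPM, 0.0502; limma-voom, 0.0882) and miR-221 in 3 (library totals only, 0.0922; limma-voom, 0.0768; a fit of the 10 libraries, 0.0888). miR-429b was not called with limma-voom (-3.94, 0.103) and miR-203a not in a fit of the 10 libraries (0.0642). Leaving out any 1 of the 10 libraries ended at least 1 of the calls of miR-10b (highest adjusted p 0.0986 without 24-month replicate 4), miR-10d (0.144 without 24-month replicate 4), miR-221 (0.110 without 24-month replicate 5), miR-203a (0.164 without 6-month replicate 2), miR-205 (0.0680 without 6-month replicate 2) and the miR-200 family (0.0658 for miR-200a without 24-month replicate 3, and without 6-month replicate 1 or 5 or 24-month replicate 1 or 5 for other members). Without the 7 libraries rich in epithelial miRNAs 17 were called, of which 14 were shared with the 63. miR-29a (adjusted p 0.0131), miR-146b, miR-1388, miR-15b, miR-15c and miR-457a were called then, while miR-29b (0.250), miR-101a (0.229) and miR-101b (0.546) were not. With both list sums as covariates miR-15b, miR-15c, miR-457a and miR-146b were called, but miR-29a (0.0522), miR-29b (0.175), miR-101a (0.211), miR-101b (0.508) and miR-1388 (0.71, SE 0.24, adjusted p 0.113) were not.

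The oldest and the youngest fish were compared at 42 and 6 months, which also differ in line. miR-29b (log2 change 1.06, SE 0.21, adjusted p 8.42e-04), miR-146b (1.01, SE 0.16, adjusted p 9.27e-05), miR-101b (0.88, SE 0.13, adjusted p 3.97e-05), miR-101a (0.78, SE 0.14, adjusted p 2.76e-04), miR-29a (0.75, SE 0.10, adjusted p 1.14e-05) and miR-1388 (0.79, adjusted p 0.00318) were higher at 42 months. miR-15c (-1.74, SE 0.21, adjusted p 5.91e-06), miR-457a (-1.40, SE 0.18, adjusted p 9.73e-06) and miR-15b (-1.23, SE 0.16, adjusted p 9.33e-06) were lower. The liver miRNA miR-122 (2.73, SE 0.88, adjusted p 0.0207), which averaged 5.52 ± 1.77 CPM at 6 and 36.6 ± 33.0 at 42 months, and miR-192 (1.82, adjusted p 0.0107) and miR-194a (1.67, adjusted p 0.0249), known from gut and liver, were higher. miR-10b went from 6271 ± 2162 to 15310 ± 2849 CPM (1.29, adjusted p 0.0279), and miR-10c (1.29), miR-222b (1.03) and miR-732 (0.86, adjusted p 0.0483) were also higher.

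The falls at 42 months included the whole miR-200 family, from -5.16 for miR-429b (SE 1.77, adjusted p 0.0279) and -4.83 for miR-429a (SE 1.38, adjusted p 0.0128) to -3.81 for miR-141. miR-375 fell by 3.88, the sensory-cell miRNAs miR-96 and miR-183 by 3.18 and 2.64, miR-203a by 2.77, miR-725 by 2.66 and miR-205 by 2.54 on the log2 scale. The red blood cell miRNAs miR-144 (-1.42, adjusted p 0.00116) and miR-451 (-1.30, adjusted p 0.00318) were lower at 42 months, and the summed CPM of these 2 went from 1818 ± 545 at 6 to 684 ± 116 at 42 months. In all, 70 of 197 miRNAs were called, 28 higher and 42 lower, with 95 at an unadjusted p under 0.05, and for 53 of the 197, 44 of them called, the ranges of the 5 libraries did not overlap (0.794% by chance). With library totals only, 16 were higher and 52 lower, and the median log2 change of all miRNAs was -0.10 in place of -0.02.

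Single libraries and limma-voom ended some of these calls at 42 against 6 months. limma-voom did not call miR-122 (1.94, adjusted p 0.189), miR-194a (1.32, 0.120), miR-732 (0.69, 0.150), miR-222b (1.02, 0.0553), miR-10b (1.35, 0.0525), miR-10c (1.41, 0.0590), miR-375 (-2.78, 0.0698) or miR-429b (-3.78, 0.0829). With library totals only miR-10c (0.0586) and miR-732 (0.0723) were not called, and in a fit of the 10 libraries miR-732 (0.0748) was not. miR-122 was not called without 42-month replicate 5 (adjusted p 0.0616) or 2 (0.0514), miR-194a without 42-month replicate 5 (0.0666) or 2 (0.0653) or 6-month replicate 4 (0.0574) or 5 (0.0534), and miR-375 (0.0546) and miR-205 (0.0546) without 6-month replicate 2. miR-10b (highest adjusted p 0.0695), miR-10c (0.0891), miR-732 (0.178 without 42-month replicate 1, 0.117 without 42-month replicate 4) and miR-429b (0.0640) lost the call without several libraries each. For miR-10b and miR-10c these were 6-month replicates 2, 4 and 5 and 42-month replicates 2 and 5, with 42-month replicate 4 for miR-10c; for miR-732 every 6-month replicate as well; and for miR-429b 6-month replicates 1 and 5 and 42-month replicates 2, 3, 4 and 5. Without the 7 epithelial-rich libraries 23 miRNAs were called, 22 of them among the 70. These included miR-101a, miR-101b, miR-146b, miR-1388 and miR-222b, and, at smaller changes, miR-429a (-2.20 in place of -4.83) and miR-200c (-1.35 in place of -3.93), but not miR-29b, miR-122, miR-192, miR-10b, miR-203a or miR-205. The change was 1.00 for miR-29b (SE 0.34 in place of 0.21), 3.01 for miR-122 (SE 1.45 in place of 0.88), 2.17 for miR-192 (SE 0.78 in place of 0.49) and 1.64 for miR-10b (SE 0.73 in place of 0.44), calls ended by larger errors with fewer libraries. It shrank to -1.14 (SE 0.69) for miR-203a, -0.91 (SE 0.66) for miR-205, -0.56 (SE 1.18, adjusted p 0.785) for miR-375, -2.05 (SE 0.68, 0.0669) for miR-96, -1.16 (SE 0.50, 0.154) for miR-183 and -1.76 (SE 0.86, 0.216) for miR-725, none of them called. With the covariates the last 4 were -0.35, -0.92, -0.46 and -0.87, and were not called. miR-222b and miR-1388 (0.76, SE 0.25, adjusted p 0.0517) were not called with the covariates either.

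At 12 against 6 months the question was what changes early in adult life, though these ages also differ in line. miR-27d rose from 1163 ± 119 to 2142 ± 432 CPM (log2 change 0.88, SE 0.18, adjusted p 0.00268), miR-732 from 25.7 ± 2.96 to 64.3 ± 22.3 CPM (1.33, adjusted p 0.0113), miR-192 from 203 ± 89.1 to 576 ± 290 CPM (1.51, adjusted p 0.0402) and miR-222b from 52.1 ± 9.67 to 117 ± 43.0 CPM (1.17, adjusted p 0.0219). miR-451 fell from 1441 ± 381 to 553 ± 133 CPM (-1.38, SE 0.30, adjusted p 0.00390), miR-34b by 1.05 (adjusted p 0.0431), miR-2188 by 0.78 (adjusted p 0.00508) and miR-216a from 218 ± 25.6 to 134 ± 17.4 CPM (-0.70, SE 0.12, adjusted p 4.19e-04). In all 28 miRNAs were called, 14 higher and 14 lower, with 70 at an unadjusted p under 0.05; 27 of the 197, 17 of them called, had ranges that did not overlap (0.794% by chance). The count was 16 without 12-month replicate 2 and 66 without 12-month replicate 4, and DESeq2 called 49. miR-222b (adjusted p 0.0681 without 12-month replicate 2, 0.0512 without 6-month replicate 3), miR-192 (0.0660 to 0.0966 without 6-month replicate 1, 3, 4 or 5 or 12-month replicate 2, 3 or 5) and miR-34b (0.0768 to 0.121 without 6-month replicate 1 or 5 or 12-month replicate 2, 3 or 5) lost the call. limma-voom did not call miR-222b (0.0707), miR-192 (0.0802) or miR-34b (0.0802), library totals only not miR-192 (0.0530) and a fit of the 10 libraries not miR-34b (0.0687). Without the 7 epithelial-rich libraries, which left 2 at 6 and 2 at 12 months, 8 miRNAs were called, with miR-27d and miR-216a among them. miR-732, miR-451, miR-2188, miR-192, miR-222b and miR-34b were not called then. With the epithelial covariates miR-216a, miR-732, miR-451 and miR-2188 were called, while miR-27d, miR-192, miR-222b and miR-34b were not.

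At 36 against 6 months, which also differ in line, miR-222b rose from 52.1 ± 9.67 to 184 ± 122 CPM (log2 change 1.82, SE 0.34, adjusted p 4.68e-04). miR-29b (1.39, SE 0.22, adjusted p 7.26e-05), miR-29a (0.82, SE 0.10, adjusted p 7.12e-06) and miR-101a (0.80, SE 0.14, adjusted p 2.49e-04) were higher. miR-15c (-1.65, SE 0.21, adjusted p 7.12e-06), miR-457a (-1.35, adjusted p 1.31e-05), miR-15b (-1.19, adjusted p 1.02e-05) and miR-214 (-1.31, SE 0.43, adjusted p 0.0427) were lower. Of 31 calls 16 were higher and 15 lower, 67 miRNAs had an unadjusted p under 0.05, and 23 of the 197, 17 of them called, had ranges that did not overlap (0.794% by chance). miR-214 alone of those named lost its call without single libraries (adjusted p between 0.0613 and 0.123 without 6-month replicate 1, 2 or 5 or 36-month replicate 2, 3, 4 or 5), as it did in a fit of the 10 libraries (0.0552). The count was 47 without 36-month replicate 1, the epithelial-rich library of that age, and 26 without all 7 such libraries, of which 19 were among the 31.

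Successive ages were compared as well. The line named differs in each of these steps, so that they cannot place changes in time apart from line. From 12 to 24 months miR-15c fell by 1.21 on the log2 scale (SE 0.21, adjusted p 0.00131), from 44.4 ± 12.1 to 19.2 ± 4.79 CPM. let-7e (0.42, SE 0.08, adjusted p 0.00232), let-7f (0.34, adjusted p 0.00632) and let-7a (0.44, adjusted p 0.0265) rose, let-7a from 47380 to 64400 CPM. miR-205 fell from 1258 ± 1179 to 131 ± 90.9 CPM (-3.27, SE 0.79, adjusted p 0.00901) and miR-725 by 2.68 (adjusted p 0.0268). There were 20 calls, 8 higher and 12 lower, with 57 at an unadjusted p under 0.05, and 8 of the 197, 7 of them called, had ranges that did not overlap (0.794% by chance).

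The calls of 24 against 12 months depended on the libraries in the fit. edgeR called 0 in a fit of the 10 libraries concerned, with 52 miRNAs at an unadjusted p under 0.05, and 0 without the 7 epithelial-rich libraries, with 24. In the full set limma-voom called 18 and DESeq2 38. The count was 31 without 12-month replicate 1, 12 without 12-month replicate 3, 13 without 12-month replicate 4 and 12 without 24-month replicate 3. let-7a lost its call without 12-month replicate 3 (adjusted p 0.0630) or 5 (0.0533) or 24-month replicate 3 (0.0553) or 4 (0.0685), and miR-725 without 12-month replicate 3 (0.0501) or 4 (0.0850) or 24-month replicate 1 (0.0577), 2 (0.0567) or 3 (0.0771). With library totals only, let-7a (0.0695) and let-7f (0.0566) were not called.

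From 24 to 36 months miR-222b rose from 63.5 ± 12.7 to 184 ± 122 CPM (log2 change 1.53, SE 0.34, adjusted p 0.0110), miR-738 from 15.1 ± 9.48 to 207 ± 179 CPM (3.78, SE 1.07, adjusted p 0.0414) and miR-142a, a miRNA of blood cells, from 310 ± 14.5 to 530 ± 158 CPM (0.77, adjusted p 0.0414). miR-92b (-0.68, SE 0.15, adjusted p 0.0110), miR-724 (-0.41, adjusted p 0.0297) and miR-181b (-0.32, adjusted p 0.0180) were lower. From 36 to 42 months 1 miRNA was called, miR-31, which went from 19.0 ± 7.80 to 6.34 ± 1.47 CPM (-1.58, SE 0.32, adjusted p 0.0121); it was also higher at 36 than at 24 months (1.79, adjusted p 0.00303) and is named outside the rule, after its values were seen. The 36-month fish alone carry Tg(pu.1:GFP).

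There were 9 calls at 36 against 24 months, 5 higher and 4 lower, and 1 at 42 against 36 months, with 42 and 29 miRNAs at an unadjusted p under 0.05. Ranges did not overlap for 9 and 4 of the 197, of which 4 and 1 were called (0.794% by chance). limma-voom did not call miR-738 (0.163), miR-222b (0.0592) or miR-142a (0.0708) at 36 against 24 months, and none of the 6 named for it was called in a fit of the 10 libraries. DESeq2 called 22 and 12, limma-voom 5 and 1, and a fit of the 10 libraries concerned 2 and 0, the latter with 26 at an unadjusted p under 0.05. Without 36-month replicate 2 the call of miR-31 in 42 against 36 months was lost and every call named for 36 against 24 months ended (adjusted p 0.0706 for miR-222b and miR-92b, 0.108 for miR-738, miR-724 and miR-181b, 0.125 for miR-142a), which left 1. Counts at 36 against 24 months were 5, 3 and 3 without 24-month replicate 2, 3 or 5 and 4 without 36-month replicate 4. miR-738 (highest adjusted p 0.131, without 24-month replicate 3) and miR-142a also lost the call without each 24-month replicate in turn. Those of miR-724 and miR-181b ended without 24-month replicate 2, 3 or 5 (highest 0.0961 and 0.0900), that of miR-738 without 36-month replicate 1 (0.0600) and those of miR-738, miR-142a and miR-724 without 36-month replicate 4 (0.111, 0.0821 and 0.0821). At 42 against 36 months edgeR called 0 without 42-month replicate 3 or 4, with 26 and 25 at an unadjusted p under 0.05, 0 without 36-month replicate 2, with 27, and 3 without 36-month replicate 3 or 5.

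Whether levels left a straight line in age was tested across the 5 groups. miR-31 peaked at 36 months at 19.0 ± 7.80 CPM against 5.50 to 11.02 at the other ages (adjusted p 0.00275). miR-190a was highest at 6 months at 220 ± 18.7 CPM and lowest at 12 months at 143 ± 10.5 (adjusted p 0.00361). miR-216a held 132 to 135 CPM from 12 months on after 218 ± 25.6 at 6 months (adjusted p 0.00775). miR-27b and miR-27d were highest at 12 months, at 27340 ± 2444 and 2142 ± 432 CPM (adjusted p 0.00775 and 0.0174).

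For departure from the line 51 miRNAs were called, with 79 at an unadjusted p under 0.05. The count was 25 without 6-month replicate 5, 23 and 32 without 12-month replicate 3 or 5, 22 without 24-month replicate 3 and 32 without 36-month replicate 1. The 5 named above kept the call without any single library and in the settings fixed beforehand; without the 7 epithelial-rich libraries miR-190a was not called, and with the covariates miR-27d was not. Departure was also called for miR-15c (adjusted p 0.0176), miR-15b (0.0476) and miR-29a (0.0303), so that a slope per year does not describe their course in full. miR-457a (0.0568) and miR-29b (0.178) were not called. Any difference between the 5 ages was called for 94 of 197 miRNAs, with 111 at an unadjusted p under 0.05. The smallest adjusted p-values were those of miR-15c (8.10e-07), miR-15b (1.86e-06), miR-457a (2.61e-06), miR-29a (3.42e-05) and miR-216a (8.65e-05).

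**Figure D3:**
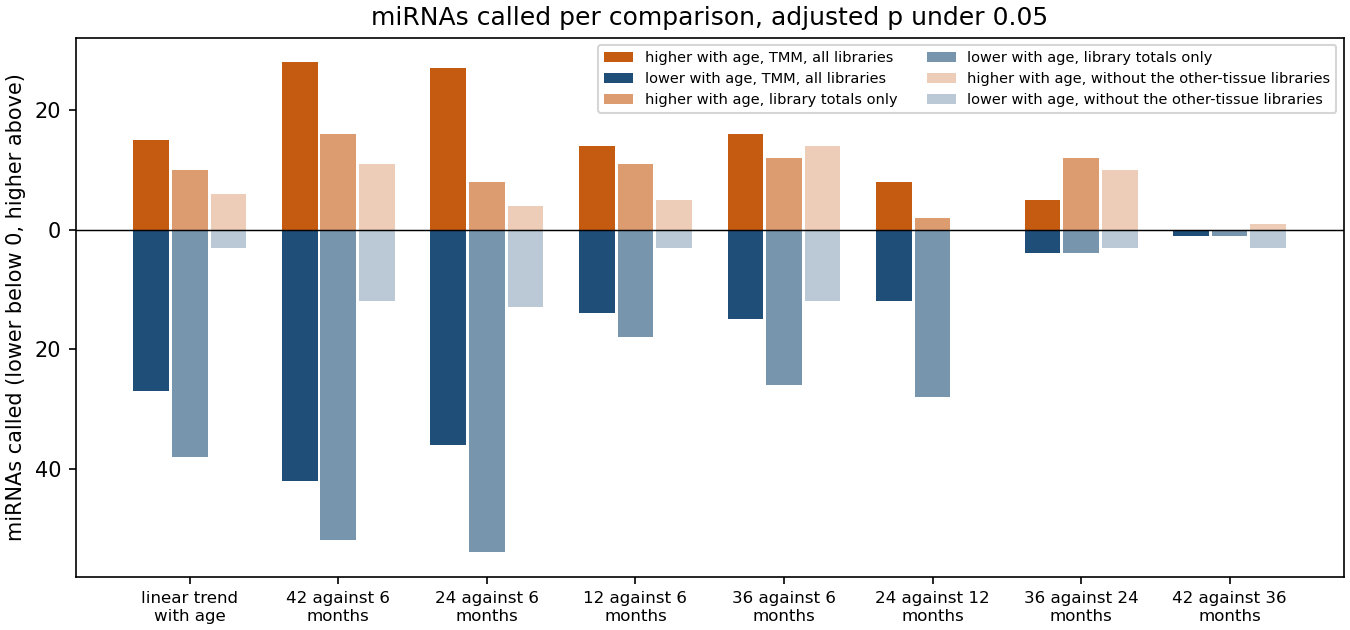
Number of miRNAs called per comparison at an adjusted p under 0.05 (higher with age above 0, lower below) with TMM and all 25 libraries, with library totals only, and without the other-tissue libraries, which are the 7 libraries above 2000 CPM for the miR-200 or the epidermis list. At 24 against 6 months 27 were higher and 36 lower with TMM, and 8 and 54 with library totals only.

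Families were tested as lists drawn up before the data were examined. In the trend, camera called the miR-29 family (adjusted p 0.00138, and 0.0339 with estimated correlation), where 2 of 2 members rose, 2 adjusted over the list alone, and miR-26/101 (adjusted p 3.33e-04, and 0.0339 with estimated correlation), where 4 of 4 rose, 4 adjusted over the list alone. miR-26a was not called with library totals only (adjusted p 0.388) or without 42-month replicate 5 (0.0560). fry called 7 lists: these 2, miR-30 (2 of 5 members fell, miR-30c and miR-30e, 2 adjusted over the list alone, median -0.08 per year), miR-15/16, red blood cells, miR-34 and epidermis. In miR-15/16, 3 of 8 members fell and miR-15a rose, 3 and 1 adjusted over the list alone (median -0.06, fry adjusted p 0.00449, camera adjusted p 0.0604). In miR-34, miR-34b and miR-34c fell, 2 adjusted over the list alone (median -0.33, fry adjusted p 0.0127); miR-34b was not called without 6-month replicate 1 (adjusted p 0.0718) or 5 (0.0557), and without the 6-month group the slopes were -0.08 for miR-34b (0.749) and -0.16 for miR-34c (0.496).

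Of the let-7 family, known for its rise as tissues mature, 2 of 10 members, let-7a and let-7j, rose in the trend and 3 did adjusted over the list alone (median 0.05 per year, camera adjusted p 0.176). let-7j was not called without 6-month replicate 2 (adjusted p 0.0751), 12-month replicate 3 or 5, 36-month replicate 5 or 42-month replicate 5. With library totals only none of the 10 rose and 1 fell. Of the miR-17-92 clusters 1 of 15 fell (miR-25, 0 adjusted over the list alone), with a median of 0.02, a mean of -0.02 and opposite directions in camera (up) and fry (down). Of miR-23/24/27, 1 of 8 fell (miR-27a, 0 adjusted over the list alone), with a median of 0.007 and a mean of -0.03. Of the list of miR-130, miR-301 and miR-454 with miR-455, 1 of 9 fell (miR-455, 1 adjusted over the list alone, median -0.009). No miR-130, miR-301 or miR-454 member was called. Of miR-181 none of 3 was called (median -0.03), or 0 adjusted over the list alone. Medians of miR-17-92 and miR-23/24/27 turned negative with library totals only. Without the 6-month group miR-455 had a slope of -0.13 (adjusted p 0.503) in place of a called one. limma-voom called neither miR-455 (adjusted p 0.0571) nor miR-27a (0.0741), and the Spearman test did not call miR-27a (0.0840). miR-25 was not called without 42-month replicate 5 (adjusted p 0.0560), miR-455 without 6-month replicate 2 (0.0783) or 5 (0.0523), and miR-27a without 6-month replicate 2 (0.0975) or 5, 12-month replicate 3, 36-month replicate 5 or 42-month replicate 1, 3, 4 or 5.

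Among lists for cells of the brain, no neuron-enriched miRNA of 16 had a trend (median 0.001 per year, camera adjusted p 0.557), and the median turned negative with library totals only. The activity-regulated miR-132 and miR-212 (median 0.06) and the endothelial miR-126a and miR-126b (0.02, of opposite signs with library totals only) were not called, also adjusted over the list alone. Of the oligodendrocyte list miR-338 rose, 1 of 2 and 1 adjusted over the list alone (median 0.08), though not with library totals only. Of 8 immune cell miRNAs miR-146b rose, 1 adjusted over the list alone, with a median of -0.01 and a mean of 0.04. The vascular smooth muscle miR-143 and miR-145 were not called (median -0.01, camera up, fry down). The Hox cluster list had 2 of 12 up, miR-125c and miR-100, and 2 adjusted over the list alone (median 0.08, camera adjusted p 0.115). Both are list members that are not Hox cluster miRNAs, and they lie within 10 kb of let-7c and let-7a. Without the 6-month group the slopes of miR-125c (0.08) and miR-100 (0.04, adjusted p 0.482) were not called.

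Of the lists for other tissues, all 3 epidermis miRNAs fell in the trend, 3 adjusted over the list alone (median -0.81 per year, camera adjusted p 0.0675, fry adjusted p 0.0151), and both red blood cell miRNAs fell, 2 adjusted over the list alone (median -0.34, fry adjusted p 0.00743), though miR-451 was not called without 6-month replicate 2 (adjusted p 0.0825), 4 (0.0512) or 5 (0.0541). limma-voom (adjusted p 0.0543) and the Spearman test (0.129) did not call miR-451 either. Without the 6-month group miR-451 had a slope of 0.006 (0.9996), miR-216a of -0.01 (0.945) and miR-217 of -0.03 (0.783). Of 6 muscle miRNAs miR-133c, miR-206 and miR-133a fell, 3 and, adjusted over the list alone, 4 (median -0.28), where miR-133c and miR-206 averaged 0.737 and 1.88 CPM at 42 months and were not called without 6-month replicate 2 (adjusted p 0.0508 and 0.0671). Neither was called with the Spearman test (adjusted p 0.111 and 0.128) or without the 6- or 42-month group, and limma-voom did not call miR-206 (-0.63, 0.0830). miR-133a was not called without the 36- or 42-month group (0.0608 and 0.0657). Of the gut, liver and pancreas list miR-216a and miR-217 fell, 2 and, adjusted over the list alone, 3 of 6, while the median (0.04) and mean (0.05) were positive and camera and fry pointed down. Of the pituitary and endocrine list miR-375 fell (1, and adjusted over the list alone 1 fell and 1 rose), with a median of 0.10, a mean of -0.25 and camera up. The miR-200 family (median -0.62, camera adjusted p 0.115), the cluster of miR-182, miR-183 and miR-96 (-0.50, camera adjusted p 0.174) and the eye, choroid plexus and pigment list (-0.18) had no member called over all tested. Adjusted over the list alone these had 0, 3 and 0 members called. miR-430b was the only tested member of its family (-0.65 per year, adjusted p 0.194), of 4 in the deposited table.

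At 42 against 6 months camera called miR-29 (adjusted p 0.00976, 2 of 2 rose), miR-26/101 (0.00976, 4 of 4 rose), the Hox cluster list (0.00976, 5 of 12 rose, 5 adjusted over the list alone, median 0.42) and miR-200 (0.0350, 6 of 6 fell, 6 adjusted over the list alone, median -4.48). With estimated correlation none of the 4 was called: the adjusted p was 0.252 for miR-29 and for miR-26/101, 0.489 for Hox and 0.557 for miR-200. fry called 11. All 3 of miR-182, miR-183 and miR-96 fell (fry adjusted p 0.0222) and all 3 epidermis miRNAs (0.0157). The former summed to 21180 and 21520 CPM in 6-month replicates 1 and 5 and 18840 in 36-month replicate 1, which are also the 3 libraries highest in the miR-200 family, against 680 to 7127 CPM in the others. Of the gut, liver and pancreas list 3 rose and 2 fell, with a median of 0.69 and a mean of 0.76 while camera and fry pointed down. Medians and means differed in sign for miR-23/24/27 (0.15 and -0.03) and the pituitary list (0.22 and -1.06), and the eye list had a median of -0.25 with camera up. With library totals only 2 miR-26/101 members and 3 members of the Hox cluster list rose.

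At 24 against 6 months camera called let-7 (adjusted p 0.0205, 4 of 10 rose, 6 adjusted over the list alone, median 0.27), miR-200 (0.0205, 6 of 6 fell, 6 adjusted over the list alone, median -4.11), miR-15/16 (0.0237, 3 of 8 fell, 3 adjusted over the list alone), Hox (0.0237, 4 of 12 rose, 4 adjusted over the list alone, median 0.34) and miR-29 (0.0456, 2 of 2 rose, 2 adjusted over the list alone). With estimated correlation none was called, each with an adjusted p of 0.569. fry called 11. All 10 let-7 members had positive changes under TMM, but 6 did and none was called with library totals only; the Hox list then had 7 of 12 positive in place of 12, and miR-26/101 2 of 4 in place of 4. Without the 7 epithelial-rich libraries, which left 2 at 6 months, none of the members of the let-7 or Hox cluster lists was called. miR-10b and miR-10d were then at 1.51 and 1.40 (SE 0.72 and 0.69, in place of 0.44 each), and miR-99 at 0.36 as before (SE 0.19 in place of 0.13), so that errors grew, while miR-100 went from 0.33 to 0.18 (SE 0.09). The 4 let-7 members called before went to 0.28 for let-7e, 0.30 for let-7c, 0.35 for let-7b and 0.09 for let-7h, in place of 0.34, 0.35, 0.44 and 0.21. In the same setting 1 of the miR-200 family was (median -1.62) and all 6 muscle miRNAs turned from negative to positive. Medians and means differed in sign for miR-23/24/27 (0.004 and -0.06) and for gut, liver and pancreas (-0.001 and 0.15).

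Whether age changes recur in other fish was tested with 24 against 6 months and 42 against 12 months, which share no library. Across 197 miRNAs, which are not independent of each other, the log2 changes had a Pearson r of 0.596 (permutation p 0.0857) and a Spearman rho of 0.486 (permutation p 0.0956), and 121 (61.4%) had the same sign. Neither passed 0.05. Without the other-tissue lists' members r was 0.427 (p 0.0780) and without the 7 epithelial-rich libraries 0.128 (p 0.441). Epithelial-rich libraries lie in both younger groups, 6 and 12 months, and in neither older one, so that the contrasts are not independent of that content. The 42- and 12-month fish also differ in line. Leaving out 42-month replicate 1 gave a p of 0.0284. With 36 in place of 42 months r was 0.152 (p 0.707).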

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

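Of the tests here, those of carried-over tissue, of the covariates, of the removal of the 7 libraries, of the transgenic line and of pooling were chosen after the data or the result were seen, and those for the miR-200 family, for 1 tissue and for the line were revised once their values were known. Library totals only, the trend without the 6-month group and 24 against 6 months were fixed beforehand, but apart from scaling for miR-15b, miR-15c and miR-457a they were put to these explanations after the results were seen. An order of handling that follows age was not tested for any pattern here and cannot be told apart from age.

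Within an age, a library stood apart when its gap to the nearest other library, divided by the range of the 5, exceeded 0.71. This held in 24 of 245 groups of 5 (9.80%), where chance gives about 1 in 20 groups. In 36-month replicate 1 miR-429b (0.924, 260 CPM against 1.53 in the nearest library), miR-141 (0.900, 2232 against 72.0 CPM), miR-200c (0.874), miR-429a (0.785), miR-200a (0.772), miR-200b (0.769) and miR-205 (0.747) were high and miR-338 (0.862, 11190 against 16950 CPM) was low. In 36-month replicate 3 miR-10c (0.784, 685 against 6509 CPM) and miR-10b (0.721, 1291 against 9595 CPM) were low. At 42 months miR-429b (0.859, 9.24 against 1.40 CPM) and miR-22a (0.757) were high in replicate 1, miR-29b (0.830, 255 against 407 CPM) and miR-26b (0.817) low in replicate 2 and miR-146b (0.736) low in replicate 4. At 24 months miR-205 (0.774) was high in replicate 4 and miR-125c (0.744) low in replicate 5. At 12 months miR-10b (0.769) was high in replicate 3 and miR-101a (0.754) in replicate 1. At 6 months miR-146b (0.757) and miR-192 (0.719) were high and miR-128 (0.748) low in replicate 2, miR-101a (0.715) high in replicate 4 and miR-21 (0.723) low in replicate 1.

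The miR-200 family, miR-203 and miR-205 were high in some libraries of 6, 12 and 36 months and low at 24 and 42 months. Scaling by TMM is argued against, since 6 of 6 miR-200 members and 3 of 3 of miR-203a, miR-203b and miR-205 kept the fall at 42 months with library totals only. Tissue carried over in single 6-month libraries is a candidate explanation for miR-203 and miR-205, since 3 of 5 such libraries lay above every 24- and 42-month library. For both lists, 1 carried-over tissue of fixed make-up is argued against by the ratio of miR-200 to skin CPM. It was 5.80 to 7.33 in 6-month replicates 1 and 5 and 36-month replicate 1 and 0.202 to 0.559 in the other 4 epithelial-rich libraries. The span of 5.18 log2 units against 2.20 among the remaining 18 does not decide this, since choosing the 7 for a high sum of either list can itself widen it. The lists did move together within ages (Spearman 0.775, permutation p 6.00e-05, Pearson on log2 values 0.675, permutation p 2.70e-04, and 0.684 without 2 libraries, over 25 libraries). For the miR-200 family 5 of 5 lay above, but the lowest exceeded the highest older library by 0.03 log2 units against a within-age SD of 0.97, so that carried-over tissue and a change with age cannot be told apart. A change of epithelial cells with age stays open and was not tested, and line differs with age as well.

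miR-15b, miR-15c and miR-457a fell together with age. The fall was already present at 24 against 6 months (log2 changes -1.12, -1.78 and -1.28). miR-15b and miR-15c departed from a straight line in age, so that their slopes do not describe a steady fall. The tables argue against the transgenic line as the whole cause, since 3 of 3 were lower at 24 than at 6 months, where no transgene is named. They argue against carried-over epithelium, since 3 of 3 kept the trend with both epithelial sums as covariates (slopes -0.36, -0.45 and -0.37 per year, in place of -0.42, -0.57 and -0.47). The covariates measure epithelial miRNAs only, so that other carried-over tissue, such as muscle or blood, was not tested. Scaling by TMM is argued against, since 3 of 3 kept the trend with library totals only, and so is pooling at 6 months, since 3 of 3 kept it without the 6-month group (-0.37, -0.43 and -0.39). Line with carried-over epithelium is argued against by 3 of 3 being called at 24 against 6 months with the covariates (adjusted p 0.00268, 4.05e-04 and 0.00424), as they were without the 7 epithelial-rich libraries (5.24e-04 each). A change with age may remain as a hypothesis, found and tested on the same data. Pooling at 6 months together with line at the later ages was not tested and stays open, and the meaning of the 2 animal numbers in the 6-month titles is unknown.

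miR-29a, miR-29b, miR-101a and miR-101b rose with age, and as whole causes the transgenic line is argued against by 4 of 4 being called at 24 against 6 months, carried-over epithelium by 4 of 4 keeping the trend with the covariates, scaling by TMM by 4 of 4 keeping it with library totals only, and pooling at 6 months by 3 of 4 keeping it without that group (miR-29a 0.13 per year, SE 0.04, adjusted p 0.0504, before 0.22, SE 0.04). Other carried-over tissue was not tested. Line together with carried-over tissue stays open, as does a change with age, since at 24 against 6 months 0 of 4 were called with the covariates: 0.43 for miR-29a (SE 0.12, adjusted p 0.0522; before 0.56, SE 0.10), 0.68 for miR-29b (SE 0.27, 0.175; before 0.76, SE 0.21), 0.35 for miR-101a (SE 0.16, 0.211; before 0.57, SE 0.14) and 0.18 for miR-101b (SE 0.15, 0.508; before 0.39, SE 0.13), calls ended by both smaller folds and larger errors. Without the 7 epithelial-rich libraries miR-29a was called there (0.50, SE 0.11, adjusted p 0.0131), while miR-29b (0.63, SE 0.33, 0.250), miR-101a (0.39, SE 0.19, 0.229) and miR-101b (0.17, SE 0.16, 0.546) were not. For these 4 pooling at 6 months together with line at the later ages was not tested and stays open. miR-26b rose by 0.12 per year (SE 0.02), and carried-over epithelium, scaling by TMM and pooling at 6 months are argued against by the call kept (1 of 1) with the covariates (0.14, SE 0.03), with library totals only (0.09, SE 0.03) and without the 6-month group (0.15, SE 0.03). For miR-26b too, other carried-over tissue, and pooling together with line, were not tested. miR-26a (0.05, SE 0.02) kept 0 of 1: larger errors ended the call with the covariates (0.06, SE 0.02, adjusted p 0.0611) and without the 6-month group (0.06, SE 0.02, 0.0879), which leaves both explanations open, whereas 0.02 with library totals only (SE 0.02, 0.388) makes scaling by TMM a candidate explanation, and line stays open for both miR-26, of which 0 were called at 24 against 6 months, with or without covariates.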

How the results depend on the processing

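The settings without the 7 epithelial-rich libraries, with the epithelial covariates and with hairpin entries not summed were chosen after the data were seen. For the named miRNAs, 4754 results under other settings kept direction and side of the threshold, 480 no longer passed, 78 without a test moved by more than the spread, 12 reversed and the remainder newly passed. With covariates the reversed values were 0.0616 for the trend of miR-203a, 0.37, 0.14 and 0.30 for miR-429b, miR-200c and miR-141 at 42 against 6 months, and 0.0903, 0.27, 0.25, 0.00803 and 0.0411 for miR-200b, miR-200a, miR-141, miR-205 and miR-203a at 24 against 6 months; the covariates are built from these miRNAs. The trend of miR-27a was 0.0139 without the 7 libraries and 0.0270 with covariates, and that of miR-451 0.00569 without the 6-month group; the cause was not tested. Without the 7 libraries the counts were 25 (any difference), 9 (trend), 19 (departure), 23, 17 and 8 (42, 24 and 12 against 6 months), 0 (24 against 12) and 4 (42 against 36); with covariates they were 34, 19, 9, 22, 7, 14, 1 and 2, and 5 for 36 against 24 months. limma-voom called 61 for any difference and 5 for 36 against 24 months. The trend had 15 calls without the 6-month group and 11 without the 42-month group, where the age range is shorter, and 65 with hairpin entries, where copies count separately. DESeq2 called 49 (12 against 6), 38 (24 against 12), 22 (36 against 24) and 12 (42 against 36), library totals 16 and a minimum of 10 CPM 5 for 36 against 24 months, and that minimum 0 for 42 against 36 months, where miR-31 is below it (edgeR, 28 at an unadjusted p under 0.05, against 12 calls by DESeq2 and 1 by limma-voom with the default filter). Fits of the 10 libraries concerned gave 0 (24 against 12), 2 (36 against 24) and 0 (42 against 36); the cause was not tested. Lists called by fry numbered 7 (trend), 11 (42 against 6) and 11 (24 against 6), by camera with estimated correlation 0 and 0 in the latter pair, and with library totals 3 at 24 against 6 months. Without miR-181a, the share of the next most abundant miRNA differed by 1.27 and 0.797 percentage points and that of the next 5 by 1.48 and 0.0419 (42 and 24 against 6 months), since another miRNA is then counted. Leaving out 1 library gave 22 to 66 calls for departure, 24 to 63 for 24 against 6, 16 to 66 for 12 against 6, 24 to 47 for 36 against 6, 12 to 31 for 24 against 12, 1 to 12 for 36 against 24 and 0 to 3 for 42 against 36 months. It gave differences of -0.80 to 0.45 in miRNAs detected at 24 against 6 months, -4.89 to -3.59 and -2.69 to -0.546 points in the share of miR-181a at 42 and 24 against 6 months, and an r of 0.427 to 0.679 between the age contrasts that share no library. All other counts stayed within 1.5 times. Simulated 1.5-fold changes were recovered at between 40% and 70%, so that smaller changes can be missed at this depth and spread.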

Other observations

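Among the tests here the comparison of neighbours, the splits of the libraries and the removal of libraries were set before their results were seen, the removals for a setting that was itself added after the data were seen, and the miRNAs described by library were chosen after their values were seen.

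Each count of calls was set against 100 splits of the same libraries into groups of the same sizes, the real split included. For any difference 1 of 100 gave as many (94 real, 24 the highest other), for the trend 1 (42 and 13), for departure 1 (51 and 30), for 42 against 6 months 1 (70 and 8), for 24 against 6 months 1 (63 and 10), for 12 against 6 months 1 (28 and 19) and for 36 against 6 months 1 (31 and 26). For 24 against 12 months 4 of 100 gave as many (20 and 27), for 36 against 24 months 2 (9 and 20) and for 42 against 36 months 3 (1 and 1). Each share lay under 0.05, the limit set beforehand, but the shares were not adjusted over the comparisons. Random splits reached the real count in each of the successive steps, so that chance is not excluded there. In the other comparisons no random split reached the real count. In 24 against 12 and 36 against 24 months the highest random split gave more calls than the real one, and what made it do so was not tested.

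Fewer libraries alone were put as an explanation of the 9 trend calls left without the 7 epithelial-rich libraries. Of 100 removals of as many libraries per age, the real one included, 9 left 9 calls or fewer. The other removals had a median of 26 and a range of 8 to 56. Only 2 libraries at 6 and 2 at 12 months are not epithelial-rich, so that every random removal also dropped epithelial-rich libraries. The removals therefore cannot separate the loss of libraries from the loss of epithelial-rich ones. Both stay open as causes of the drop.

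miRNAs that lie within 10 kb of each other, and that are often read from 1 transcript, were tested for alike age trends. Across 82 neighbouring pairs of 80 miRNAs the median absolute difference of slopes was 0.0533 log2 units per year against 0.183 for random pairs, with p 1.00e-04, the smallest that 10000 permutations can give, and 62 pairs had slopes of the same sign. This is consistent with shared transcription of neighbours. Pairs of a family can also share reads. miR-15b and miR-457a (-0.42 and -0.47 per year) are neighbours, whereas miR-15c (-0.57) and its neighbour miR-16a (-0.12, adjusted p 0.179) moved less alike.

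miR-735 had 0 counts in 42-month replicates 1 and 5, which allows up to 0.372 and 0.420 CPM, against 262 to 825 CPM in every other library. miR-2185 was at 21.2 and 10.4 CPM in 12-month replicates 3 and 4 and at 38.2, 22.6 and 26.8 CPM in 36-month replicates 3, 4 and 5, against 231 to 571 CPM elsewhere. miR-122 was at 37.3, 38.0 and 58.5 CPM in 12-month replicates 2, 3 and 5 and at 22.3, 69.0 and 74.7 CPM in 42-month replicates 1, 2 and 5. The first principal component held 43.9% of the variance. Its largest loadings were those of the 6 miR-200 family members, led by miR-429a and miR-429b, followed by miR-205. At its low end lay 6-month replicates 1, 2 and 5 (-12.74, -9.878 and -13.75), 12-month replicate 4 (-12.77) and 36-month replicate 1 (-11.72), all epithelial-rich. The epithelial-rich 12-month replicates 3 and 5 (-1.364 and -2.109) lay among the other libraries. The component thus follows the epithelial content described above in part. No explanation was tested for the levels of miR-735, miR-2185 and miR-122 or for this component.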
